A study of Mus musculus with 12 samples.

How the data were processed

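RNA from 12 mouse liver cell cultures was measured by paired-end RNA sequencing. Per the labels' protocols, libraries were made from 1 μg of total RNA with a stranded mRNA kit that selects polyadenylated RNA, and inserts of 200 to 400 bp were kept. Per the submitters' processing notes, reads were aligned with HISAT2 and transcripts quantified with StringTie on the mouse build mm10; no version, annotation release or strand setting is given for either. Per the file headers, the deposited gene table holds for each library an estimated count of reads (expected count), and values normalised to TPM and FPKM. The deposited counts are whole numbers, and whether both mates of a pair were counted is not stated. The authors' TPM values were used only for 1 alternative, and their FPKM values were not used. Per the file headers, the deposited transcript table gives each transcript's length and locus, which supplied gene lengths and coordinates. The gene table lists 45777 genes by symbol and NCBI Gene number. Of these, 45679 have an entry of the same number in a RefSeq annotation of GRCm38.p6, and 44354 start at the same base there. Coordinates are therefore given 1-based on mm10, as the span of a gene's transcripts in the deposited table.

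The titles of the co-culture libraries name both cells. The first-named cell was taken as the one whose RNA was sequenced, and marker genes were used to check it. This gave 4 groups of 3 libraries, which are Hepa1-6 cells and liver sinusoidal endothelial cells (LSECs), each in mono-culture and in co-culture. Total counts ranged from 32761492 to 48870698 per library, so that 3 counts, the most that a count of 0 allows, correspond to 0.0614 to 0.0916 CPM. Such limits cover counting error only, since PCR copies are not independent molecules.

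Each comparison was fitted with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood F-test was used with Benjamini-Hochberg adjustment at 0.05. The Hepa1-6 comparison, the LSEC comparison and the comparison of the mono-cultures each used their own 6 libraries. The test of whether the co-culture effect differs between the cell types used all 12. Standard errors of log2 fold changes were derived from the F statistic. CPM values were computed on 1 TMM scale over the 12 libraries and are given as mean ± SD with n = 3 unless stated. Gene lists were compared with all other tested genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. This covered 27 pathway lists with at least 5 tested members. Camera with an estimated correlation was run beside it. So was fry, which tests a list against no change and not against the other genes. The lists, 11 marker lists, the rule for named genes, the tests and the alternatives were written before the data were examined. Shared calls were compared by Fisher's exact test, two-sided. The co-cultured cells shared wells but the compared groups shared no library.

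Named genes had an adjusted p under 0.05, co-culture values all on one side of the mono-culture values and a mean of at least 5 CPM. From these the 10 with the largest rise and the 10 with the largest fall were taken, then the 6 with the largest rise that were lower in the other cell's mono-culture than in their own co-culture. From each pathway list described, up to 4 members with the smallest p were named. For the mono-cultures the 4 largest differences each way at a mean of at least 50 CPM were named with marker list members, and for the difference between the cell types the 5 smallest p each way. Predicted gene models were counted but not named.

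Carry-over of RNA between the cells was estimated from diagnostic genes at least 100-fold higher in the other cell's mono-culture, with at least 20 CPM there. The estimate is the median over those genes of the gain over the own mono-culture, as a percent of the difference between the cells. Genes with near-identical relatives (major histocompatibility genes, CXC chemokines, ribosomal proteins with pseudogenes) are uncertain, since the handling of shared reads is not stated. The same holds for antisense and overlapping genes.

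Samples that share a replicate number were checked for shared deviations from their group means. The correlations of same-numbered LSEC libraries were 0.654, 0.292 and 0.33, all above the limit of 0.1 fixed for pairing, although replicates 2 and 3 correlated as well with each other's number (0.309 and 0.353). The blocked fit, with replicate number as a term, is therefore given beside the LSEC results. Same-numbered Hepa1-6 libraries correlated at -0.006, -0.024 and -0.026, and were not treated as pairs.

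The tests were tried on simulated data with 200 changed genes. For the Hepa1-6 comparison (14542 genes), 61.2% of genes changed 1.5-fold, 79.1% at 2-fold and 97% at 4-fold were recovered. For the LSEC comparison without replicate structure (14955 genes), 0%, 3% and 63.6% were recovered, with 10.2% of calls false. With the replicate structure kept (14997 genes), the LSEC fit without the block recovered 0%, 0% and 33.3%. The blocked fit recovered 67.2%, 88.1% and 95.5%, with 6.2% of its calls false. The replicate effect was drawn the same for both cultures there, which favours the blocked fit. For the difference between the cell types (17004 genes), 0%, 9% and 37.9% were recovered. The spread was drawn the same for both cell types there, unlike in the real libraries. For the mono-cultures (15906 genes), 1.5%, 23.9% and 74.2% were recovered. The carry-over estimate returned 0.99% and 4.98% when 1% and 5% were mixed in.

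Alternatives were RLE size factors, DESeq2 1.42.0, limma on log2(TPM + 1), other filters, a 2-fold limit, a shared dispersion, a restriction to genes not higher in the other cell, and leaving out each library. After seeing the data, fits with replicates 2 and 3 only and with a term for LSEC replicate 1 were added. GC content was taken from GENCODE M21 transcripts by symbol.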

Results

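The study asked how a mouse hepatoma line and primary liver endothelium change each other's transcripts when grown in the same well. Hepa1-6 is a mouse hepatoma cell line. LSECs are the fenestrated endothelial cells that line the liver's capillaries. LSECs (500000 per well) sat at the bottom of a 12-well plate and Hepa1-6 cells (100000) in an insert with 3 μm pores, so the medium was shared. Both were kept for 24 h in medium with 2% serum, together or alone. There were 3 libraries for each of 4 groups. Total counts were 32761492, 38294378 and 42380482 for co-cultured Hepa1-6 cells, and 34983916, 43525113 and 43159040 for Hepa1-6 cells alone. They were 43941801, 38277204 and 36590767 for co-cultured LSECs, and 48870698, 35991850 and 35459408 for LSECs alone.

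The mono-cultures were compared to learn which cell each library held. LSECs alone carried endothelial transcripts at high levels and Hepa1-6 cells alone carried those of several secreted liver proteins. Cdh5, the endothelial cadherin, was at 3257 ± 1075 CPM in LSECs and had no count in Hepa1-6 cells, which is at least 138000-fold higher against a floor of 3 counts over the group. The vascular genes Robo4 and Mmrn2 were at 1085 ± 5.17 and 1027 ± 206 CPM in LSECs, also with no count in Hepa1-6 cells. The class I histocompatibility gene H2-K1 was at 1344 ± 379 CPM in LSECs and likewise had none. In the other direction Pnma5, Cxcl15, Bche (butyrylcholinesterase) and Serpinb7 stood at 236.1, 227.2, 213.2 and 124.5 CPM in Hepa1-6 cells and had no count in LSECs. Albumin (Alb) was at 2031 ± 32.9 CPM in Hepa1-6 cells and 7.35 ± 2.64 CPM in LSECs, and Afp, the fetal serum protein, at 1544 ± 36.7 and 2.21 ± 1.19 CPM. All 20 tested sinusoidal endothelial markers and all 23 pan-endothelial markers were higher in LSECs. Of 21 tested hepatoma and hepatocyte secretory markers, 15 were higher in Hepa1-6 cells and 4 in LSECs. Of 20 mature hepatocyte markers only 2 reached 1 CPM in Hepa1-6 cells alone, and of 6 tested 2 were higher there and 3 in LSECs. edgeR called 11487 of 16411 genes, 6107 higher in LSECs and 5380 higher in Hepa1-6 cells.

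The LSEC libraries also held transcripts of other liver cells. All 20 macrophage and Kupffer cell markers were at 1 CPM or more and higher in LSECs than in Hepa1-6 cells, led by Lyz2 (603 ± 137 CPM), Marco (575 ± 188 CPM) and Cd5l (428 ± 76.6 CPM). Of 19 stellate cell and fibroblast markers, 11 reached 1 CPM in LSECs alone, with Col1a1 at 32.5 ± 7.78 CPM. Of the T and NK cell markers 1 of 15 reached that level, of the B cell markers 2 of 10, of the neutrophil markers 1 of 10, and of the cholangiocyte and mesothelium markers 5 of 11.

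Carry-over of RNA between the cells was small in every co-culture library. Over 404 genes diagnostic of LSECs, the median gain in co-cultured Hepa1-6 libraries was 0% of the LSEC level in each of 3 libraries. Over 190 genes diagnostic of Hepa1-6 cells, it was 0% in each of 3 co-cultured LSEC libraries. Summed over the genes, the Hepa1-6 set stood at 0.275% to 0.306% of its Hepa1-6 level in LSECs alone and at 0.457% to 0.597% in co-cultured LSECs. The LSEC set stood at 0.13% to 0.133% in Hepa1-6 cells alone and at 0.142% to 0.146% in co-culture. Cdh5 had no count in co-cultured Hepa1-6 cells, and Alb was at 10.3 ± 3.66 CPM in co-cultured LSECs. The markers thus placed the co-culture libraries with the first cell in their titles.

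In Hepa1-6 cells, co-culture raised a few genes strongly and moved many genes a little. Il11, a cytokine of the interleukin-6 family, rose 22.7-fold, from 0.451 ± 0.0857 to 10.25 ± 0.151 CPM. Ramp3, a partner of the adrenomedullin receptor, rose 16.9-fold, from 3.21 ± 0.33 to 54.5 ± 4.9 CPM. Ass1, a urea cycle enzyme, rose 7.11-fold, from 7.85 ± 0.679 to 55.7 ± 6.29 CPM, and Cyp1a1, a xenobiotic-metabolising enzyme, rose 4.03-fold, from 96.4 ± 3.52 to 388 ± 20.7 CPM. Ccl20, a chemokine, showed the largest named fall, 1.78-fold, from 21.87 ± 1.13 to 12.26 ± 0.469 CPM.

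Il11 (Gene 16156) lies on chromosome 7 at 4772373 to 4782907, Ramp3 (56089) on chromosome 11 at 6658506 to 6677478, Ass1 (11898) on chromosome 2 at 31470270 to 31520670, and Ccl20 (20297) on chromosome 1 at 83116766 to 83119167, all on mm10. The log2 fold changes of Il11, Ramp3, Ass1 and Cyp1a1 were 4.51 (SE 0.16), 4.08 (SE 0.09), 2.83 (SE 0.08) and 2.01 (SE 0.04), with adjusted p of 1.5e-14, 2.11e-18, 6.32e-14 and 1.37e-17. The other large rises were Dclk1 (5.44-fold), Slc17a6 (3.92-fold), Fam20a (3.21-fold), Cntnap5a (3.18-fold), Krt33b (2.67-fold) and Syt13 (2.45-fold). All of these 10 genes but Fam20a were lower in LSECs alone than in co-cultured Hepa1-6 cells; Il11 was at 0.549 ± 0.0999 CPM in LSECs alone. The other named falls were between 1.47-fold and 1.6-fold. They were Pdgfb, a platelet-derived growth factor chain, the glycine transporter Slc6a9, Tnnt2, the TAM receptor ligand Gas6, the protease Pcsk6, Fam129a, Apela, Abcd2 and Trib3, with log2 fold changes from -0.68 to -0.55.

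edgeR called 2298 of 14796 genes, 1258 higher and 1040 lower. Of these, 98 were higher and 13 lower by at least 2-fold, and the median absolute log2 fold change of the called genes was 0.19. With limma on log2(TPM + 1) the split was 864 higher and 423 lower. The co-culture and mono-culture ranges did not overlap for 30.6% of the tested genes, where chance gives 10%. Read counts within a Hepa1-6 group differed little, at a chi-square per degree of freedom of 3.223 to 5.835, where sampling noise alone gives 1. The labels do not say whether replicates were separate cultures, so the p-values may rest on spread between wells only.

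**Figure D1:**
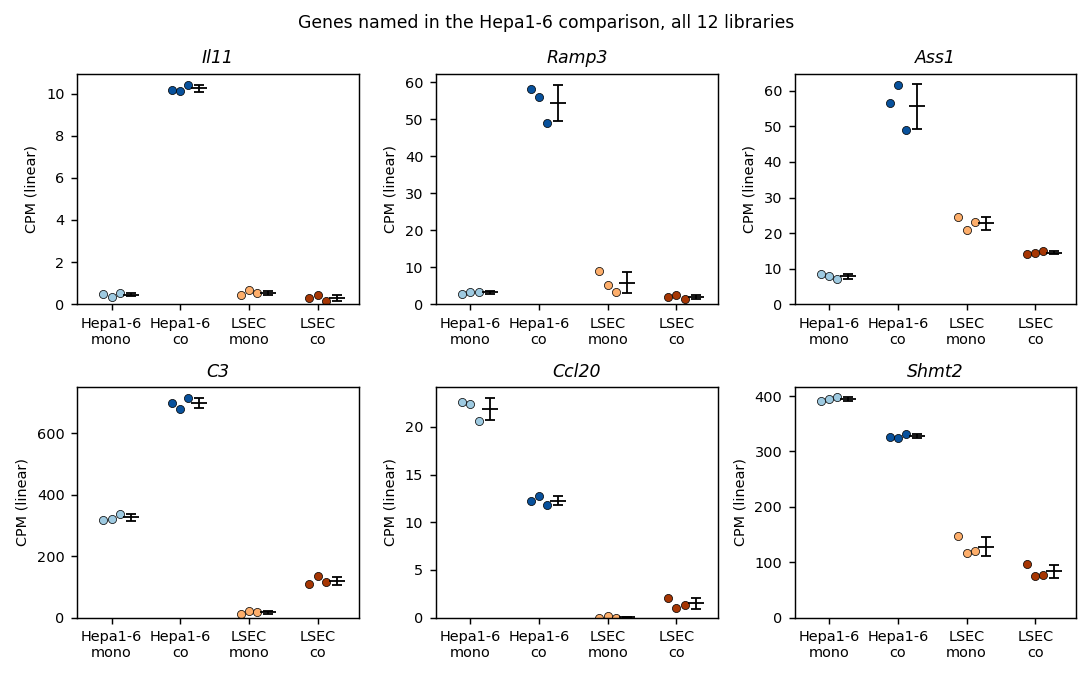
CPM (linear axis) of 6 genes in all 12 libraries, with a dot per library and a bar for mean and SD (n = 3). Il11, Ramp3, Ass1 and C3 were higher and Ccl20 and Shmt2 lower in every co-cultured Hepa1-6 library than in every Hepa1-6 library grown alone.

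Most acute phase genes tested rose in co-cultured Hepa1-6 cells. Of 11 tested list members 8 rose, 0 fell and 3 did not pass the test (10 rose when adjusted over the list alone). Complement C3 went from 326 ± 10.8 to 698 ± 16.7 CPM, the lipopolysaccharide-binding protein Lbp from 146 ± 2.43 to 219 ± 7.99 CPM, ceruloplasmin (Cp) from 25.3 ± 0.582 to 40.8 ± 0.637 CPM and hemopexin (Hpx) from 65.9 ± 1.74 to 85.7 ± 4.65 CPM. The list was higher by camera (adjusted p = 1.71e-27) and with an estimated correlation (adjusted p = 0.0262). Of 16 TGF-beta and BMP targets 9 rose and 0 fell, also 9 when adjusted over the list alone, among them Tgfbr1 (log2 fold change 0.41), Ccn2 (0.39) and Id2 (0.32). Camera gave an adjusted p of 1.46e-10, or adjusted p = 0.0262 with an estimated correlation. These were the only pathway lists of the 14 past the threshold in Hepa1-6 cells that passed with an estimated correlation.

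Part of the integrated stress response list, a translation-control program driven by the factor ATF4, fell in co-cultured Hepa1-6 cells. Of 25 tested members 13 fell and 2 rose (15 and 2 when adjusted over the list alone). Shmt2, a serine and folate enzyme, went from 395 ± 3.92 to 328 ± 3.69 CPM. The amino acid transporter Slc7a5, the proline enzyme Aldh18a1 and the serine synthesis enzyme Psat1 had log2 fold changes of -0.33, -0.33 and -0.23. The list median was -0.21, and camera gave an adjusted p of 1.46e-10, with adjusted p = 0.1 with an estimated correlation. Of 40 ribosomal protein genes 23 fell (32 when adjusted over the list alone), with a list median of -0.10; the adjusted p was 2.87e-09 by camera and adjusted p = 0.414 with an estimated correlation. Among them Rps2 went from 2193 ± 34.5 to 2002 ± 50 CPM.

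Some hypoxia, unfolded protein response, glycolysis and matrix genes rose slightly. Of 21 hypoxia genes 12 rose and 0 fell (13 adjusted over the list alone), including the mitophagy gene Bnip3, from 28.8 ± 1.69 to 51.4 ± 5.38 CPM, and Ndrg1, from 49.5 ± 0.778 to 69.0 ± 3.92 CPM. Of 20 unfolded protein response genes 12 rose and 0 fell (15 adjusted over the list alone), among them Dnajc3, Xbp1, Hyou1 and the chaperone Hspa5 with log2 fold changes of 0.28, 0.24, 0.15 and 0.11. Of 18 glycolysis genes 8 rose and 0 fell (10 adjusted over the list alone), with Aldoa from 1222 ± 22.1 to 1367 ± 36.2 CPM. Of 32 matrix remodelling genes 14 rose and 1 fell (16 and 2 adjusted over the list alone); Nid1, a basement membrane protein, had a log2 fold change of 0.52 and osteopontin (Spp1) one of -0.47. Camera adjusted p values were 9.35e-10, 2.3e-05, 0.00014 and 9.03e-05 in that order. With an estimated correlation they were adjusted p = 0.168, 0.168, 0.287 and 0.176.

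Inflammatory genes moved both ways in Hepa1-6 cells. Of 24 tested, 8 rose and 4 fell (the same counts adjusted over the list alone). The NF-kB inhibitors Nfkbia and Tnfaip3 had log2 fold changes of 0.44 and 0.56, and Ccl20 and the adhesion molecule Vcam1 of -0.83 and -0.51; camera gave an adjusted p of 0.39. Of 29 interferon response genes 7 rose and 0 fell (7 adjusted over the list alone), with the sensor Ddx58 from 61.9 ± 3.67 to 82.8 ± 4.87 CPM and an adjusted p of 0.0015 by camera, or adjusted p = 0.176 with an estimated correlation. Of 23 immediate early genes 9 rose and 5 fell (the same adjusted over the list alone), among them Ier3 (log2 fold change 0.88), Dusp1 (0.90), Fosl2 (0.66) and Myc (-0.41). Camera gave an adjusted p of 0.0292, or adjusted p = 0.176 with an estimated correlation. Of 48 cell cycle genes 4 rose and 1 fell, with an adjusted p of 0.538 by camera. Of the hepatoma and hepatocyte secretory markers 9 of 17 rose and 0 fell; Alb went from 2031 ± 32.9 to 2304 ± 96 CPM and Afp from 1544 ± 36.7 to 1939 ± 72.5 CPM.

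Another 4 lists passed by camera in Hepa1-6 cells. Of 16 tip cell and angiogenesis genes 4 rose and 2 fell (5 and 2 adjusted over the list alone), with Ramp3, Igfbp3, Pdgfb and Vegfc the most certain. Of 9 shear-responsive genes 4 rose and 1 fell (5 and 1 alone), led by Slco2a1 and Procr, and of 25 NRF2 targets 7 rose and 1 fell (8 and 1 alone), led by the quinone reductase Nqo1 (log2 fold change 0.88). Of 28 nuclear oxidative phosphorylation genes 1 rose and 3 fell, also when adjusted over the list alone, with a list median of -0.05. Camera adjusted p values were 4.1e-06, 9.55e-05, 0.00354 and 0.0226, and with an estimated correlation adjusted p = 0.0834, 0.149, 0.132 and 0.54. The other 13 lists did not pass. For 4 of those the list median and camera's direction differed in sign, namely Notch (median -0.015, camera up), p53 targets (-0.017, up), fatty acid synthesis (0.033, down) and cholesterol synthesis (0.003, down). Few markers of the other cells moved in Hepa1-6 cells. Of 7 sinusoidal endothelial markers tested 2 rose and 0 fell, and of 9 pan-endothelial markers 1 rose and 1 fell. Of 10 continuous, arterial and venous markers 2 rose and 2 fell, and of 7 macrophage markers 1 rose and 0 fell.

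In LSECs, co-culture raised inflammatory genes by large factors. Il1b, encoding interleukin-1 beta, rose 122-fold, from 3.34 ± 1.38 to 424 ± 133 CPM. Il6 rose 95.9-fold, from 0.667 ± 0.317 to 65.8 ± 12.1 CPM, and Csf3, the granulocyte colony-stimulating factor, 67.9-fold, from 1.42 ± 0.375 to 100.5 ± 34 CPM. The largest fall was in Trem2, a lipid-sensing receptor of macrophages, which went from 26.9 ± 12.5 to 1.37 ± 1.13 CPM. The growth factor Igf1 fell 12.1-fold, from 32.3 ± 1.93 to 2.72 ± 0.864 CPM.

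Il1b (Gene 16176) lies on chromosome 2 at 129364569 to 129371164, Il6 (16193) on chromosome 5 at 30013114 to 30019975, Csf3 (12985) on chromosome 11 at 98700183 to 98703631, Trem2 (83433) on chromosome 17 at 48346401 to 48352276, and Igf1 (16000) on chromosome 10 at 87858265 to 87937047, all on mm10. Their log2 fold changes were 6.93 (SE 0.46), 6.58 (SE 0.39), 6.09 (SE 0.38), -4.32 (SE 0.68) and -3.60 (SE 0.27), with adjusted p of 0.00152, 0.00114, 0.00125, 0.0285 and 0.00227. The other large rises were Il12b (142-fold), Tmc3 (104-fold), the gelatinase Mmp9 (97.1-fold), the anti-inflammatory cytokine Il10 (82.3-fold), the neutrophil chemokine Cxcl3 (73.6-fold), Slc13a3 (62.7-fold) and Ms4a4a (56.5-fold). Il12b, Il1b, Tmc3, Il6 and Il10 had no count in Hepa1-6 cells alone. Mmp9 was at 4.66 ± 0.161 CPM there, below its 86.9 ± 14.7 CPM in co-cultured LSECs. The other large falls were Cd300a (7.17-fold), Rgs1 (6.79-fold), the lectin Lgals3 (5.85-fold), Arhgap19 (5.43-fold), Cd300lb (4.62-fold), Gpnmb (4.6-fold), Aph1c (4.18-fold) and Atf5 (4.12-fold).

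edgeR called 471 of 15256 genes, 332 higher and 139 lower, of which 289 and 100 changed by at least 2-fold. With the replicate block the count was 5082, with 2550 higher and 2532 lower, and all 471 genes were among them with the same sign. Replicate 1 of both LSEC cultures differed from replicates 2 and 3, with short transcripts higher and long ones lower. With replicates 2 and 3 only, an alternative chosen after seeing the data, 5559 genes passed. Read counts of replicates 2 and 3 differed little, at a chi-square per degree of freedom of 4.155 in co-culture and 5.318 in mono-culture. Sampling noise alone gives 1. Replicate 1 differed from them by 181.7 to 295.8. The labels do not say whether replicates were separate preparations, so the 5559 and 5082 calls may rest on spread between wells only. The count without the block was 293, 146 and 160 when co-culture replicate 1, 2 or 3 was left out, 155 and 150 without mono-culture replicate 2 or 3, and 490 without mono-culture replicate 1. The ranges of the groups did not overlap for 21.6% of the tested genes. Chance gives 10% for independent libraries, which the LSEC libraries, with deviations shared by replicate number, are not.

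**Figure D2:**
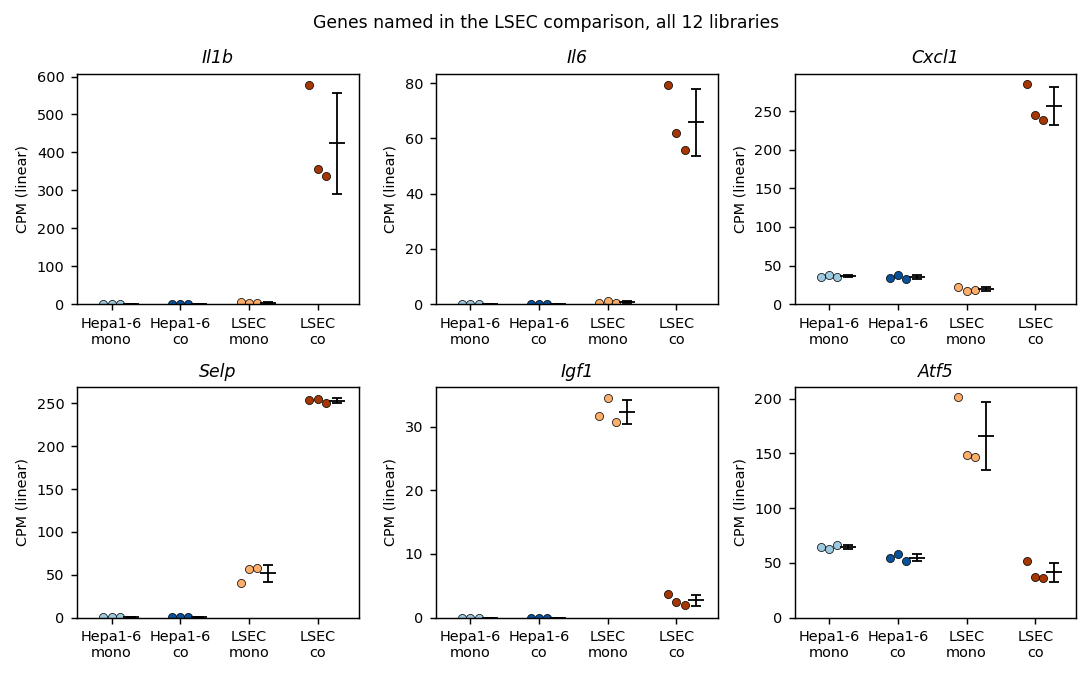
CPM (linear axis) of 6 genes in all 12 libraries, with a dot per library and a bar for mean and SD (n = 3). Il1b, Il6, Cxcl1 and Selp were higher and Igf1 and Atf5 lower in every co-cultured LSEC library than in every LSEC library grown alone.

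Of 34 inflammatory cytokine and NF-kB target genes 23 rose and 0 fell in LSECs (33 rose when adjusted over the list alone, and 33 with the replicate block). Interleukin-1 alpha (Il1a) went from 22.0 ± 3.36 to 626 ± 21.9 CPM, and the neutrophil chemokines Cxcl1, Cxcl2 and Cxcl5 from 19.7 ± 2.57 to 256 ± 24.7, from 17.2 ± 2.41 to 234 ± 34.5 and from 0.797 ± 0.207 to 17.6 ± 1.12 CPM. The list median was a log2 fold change of 2.00, with an adjusted p of 8.7e-55 by camera and adjusted p = 0.0355 with an estimated correlation. Of 21 acute phase and STAT3 target genes 8 rose and 0 fell (14 adjusted over the list alone, and 14 with the block). Among them were the interleukin-1 antagonist Il1rn, from 13.6 ± 1.72 to 194 ± 10.6 CPM, and Socs3, from 24.4 ± 1.68 to 122 ± 22.1 CPM. Camera gave an adjusted p of 4.26e-20, or adjusted p = 0.0355 with an estimated correlation. These 2 of the 10 lists past the threshold in LSECs passed with an estimated correlation, and with the block neither did (adjusted p = 0.144 for both).

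Macrophage markers moved beside these genes, and not in one direction. With the replicate block, 10 of the 20 rose and 5 fell; without it 3 rose and 2 fell. Adgre1 (F4/80) went from 119 ± 21.8 to 533 ± 55.7 CPM, Itgam from 11.1 ± 4.89 to 253 ± 75 CPM and Cd14 from 57.4 ± 14.5 to 228 ± 71.6 CPM. The Kupffer cell markers Cd5l and Vsig4 went from 428 ± 76.6 to 128 ± 22.5 CPM and from 69.5 ± 11.7 to 17.6 ± 0.84 CPM. Clec4f and Marco, of the same cells, were higher with the block (adjusted p = 0.0173 and 2.16e-05, against 0.925 and 0.386 without it). Csf1r was at 134 ± 16.7 and 127 ± 4.4 CPM (adjusted p = 0.865, or 0.177 with the block). Neutrophil markers S100a8, Csf3r and Mmp8 rose, to 10.2 ± 4.49, 34.3 ± 0.782 and 27.5 ± 2.1 CPM. The B cell marker Ighm rose from 2.42 ± 0.527 to 10.7 ± 0.761 CPM, the only 1 of 9 to pass, and with the block 2 rose and 1 fell.

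Endothelial markers stayed high in co-cultured LSECs. Of 21 tested sinusoidal markers 2 rose and 0 fell, and with the block 17 rose and 0 fell. Fcgr2b, the scavenging Fc receptor, went from 569 ± 49.5 to 1048 ± 42.9 CPM and Bmp2 from 107 ± 10.6 to 263 ± 23.9 CPM. Of 23 pan-endothelial markers 0 passed without the block, while 10 rose and 7 fell with it. Of 18 markers of continuous, arterial and venous endothelium 4 rose and 0 fell (11 and 4 with the block). The leukocyte adhesion molecules Selp and Sele went from 51.6 ± 10.2 to 253 ± 2.6 CPM and from 16.8 ± 4.42 to 80.7 ± 9.21 CPM, the chemokine receptor Ackr1 from 1.79 ± 1.05 to 36.3 ± 15 CPM and Cd34 from 34.0 ± 1.56 to 79.0 ± 1.3 CPM. Of 18 tested stellate cell markers, 9 cholangiocyte and mesothelium markers, 4 mature hepatocyte markers and 4 T and NK cell markers, 0 passed without the block. With it 4 stellate cell markers rose and 4 fell, 4 cholangiocyte and mesothelium markers fell, 1 mature hepatocyte marker rose and 1 fell, and 1 T and NK cell marker fell.

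Some integrated stress response genes fell in LSECs as well. Of 26 tested 10 fell and 1 rose (18 and 1 adjusted over the list alone, 20 and 2 with the block), and the list median was a log2 fold change of -0.91. The folate enzyme Mthfd2 went from 76.8 ± 7.25 to 25.3 ± 3.82 CPM, the factor Atf5 from 166 ± 31.3 to 41.5 ± 8.63 CPM, Slc7a5 from 95.9 ± 11.3 to 42.8 ± 3.92 CPM and the glutathione-degrading enzyme Chac1 from 21.5 ± 2.07 to 5.88 ± 1.55 CPM. Camera gave an adjusted p of 2.12e-14, with adjusted p = 0.0957 with an estimated correlation. Of 20 YAP/TEAD targets 5 fell and 0 rose (8 fell and 1 rose adjusted over the list alone, 12 and 2 with the block), among them Ajuba, Ankrd1, Axl and Ccn1, with log2 fold changes of -0.84, -1.18, -1.10 and -0.73. The adjusted p was 0.000142 by camera and adjusted p = 0.332 with an estimated correlation. Caveolin-1 (Cav1), of the shear-responsive list, went from 261 ± 36.8 to 83.5 ± 5.9 CPM.

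Of 34 interferon response genes 6 rose and 1 fell (13 and 1 adjusted over the list alone, 22 and 1 with the block), with the GTPase Gbp2 from 28.3 ± 1.96 to 88.2 ± 2.79 CPM. Of 22 antigen presentation genes 2 rose and 0 fell (6 adjusted over the list alone, 19 with the block); these were the checkpoint ligand Cd274, from 18.4 ± 3.85 to 73.5 ± 11 CPM, and H2-Ab1, from 2.34 ± 0.842 to 12.6 ± 4.64 CPM. Camera adjusted p values were 1.27e-07 and 4.07e-05, with adjusted p = 0.177 and 0.423 with an estimated correlation. Of 40 matrix remodelling genes 5 rose and 1 fell (8 and 2 adjusted over the list alone, 15 and 8 with the block), and the collagenase Mmp13 went from 19 ± 3.17 to 330 ± 13.7 CPM. For cell cycle genes, 0 of 47 passed without the block, while 1 was higher and 19 lower with it; NRF2 targets had 1 higher and 1 lower of 25, and 2 higher and 16 lower with the block. The mitochondrially encoded list had 0 of 13 past the threshold and 11 higher with the block. Camera adjusted p values for these 4 lists were 0.0267, 0.000102, 0.035 and 0.00266, and with an estimated correlation adjusted p = 0.549, 0.138, 0.401 and 0.177. Ribosomal proteins did not pass without the block (adjusted p = 0.267). With it 1 was higher and 15 lower of 40, with an adjusted p of 0.00995 by camera and adjusted p = 0.803 with an estimated correlation; without mono-culture replicate 1 and without the block the direction was up (adjusted p = 0.0708). The other lists did not pass in LSECs. The median was above 0 and camera's direction down for tip cell and angiogenesis (0.087), Notch (0.117) and secreted growth factors (0.055), with adjusted p of 0.882, 0.891 and 0.375.

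**Figure D3:**
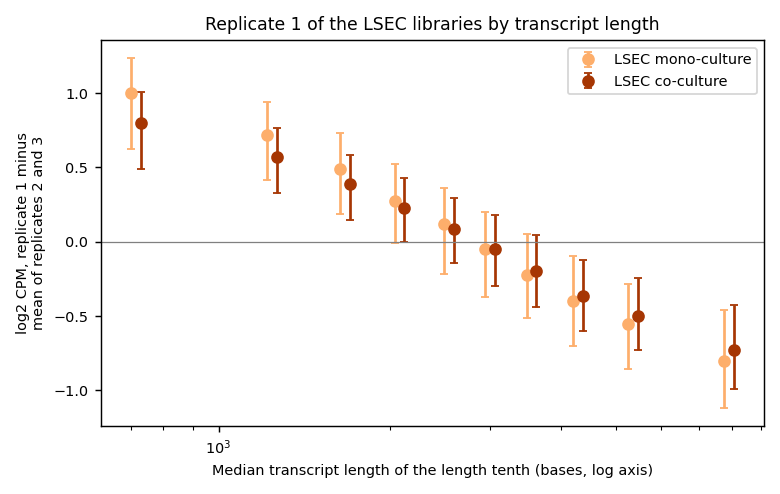
Shift of LSEC replicate 1 from the mean of replicates 2 and 3 (log2) against transcript length, in 10 bins of equal gene number for both cultures, with dots for medians and bars for quartiles. The median shift went from 1.00 and 0.80 in the shortest bin to -0.80 and -0.73 in the longest, in mono-culture and co-culture.

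**Figure D4:**
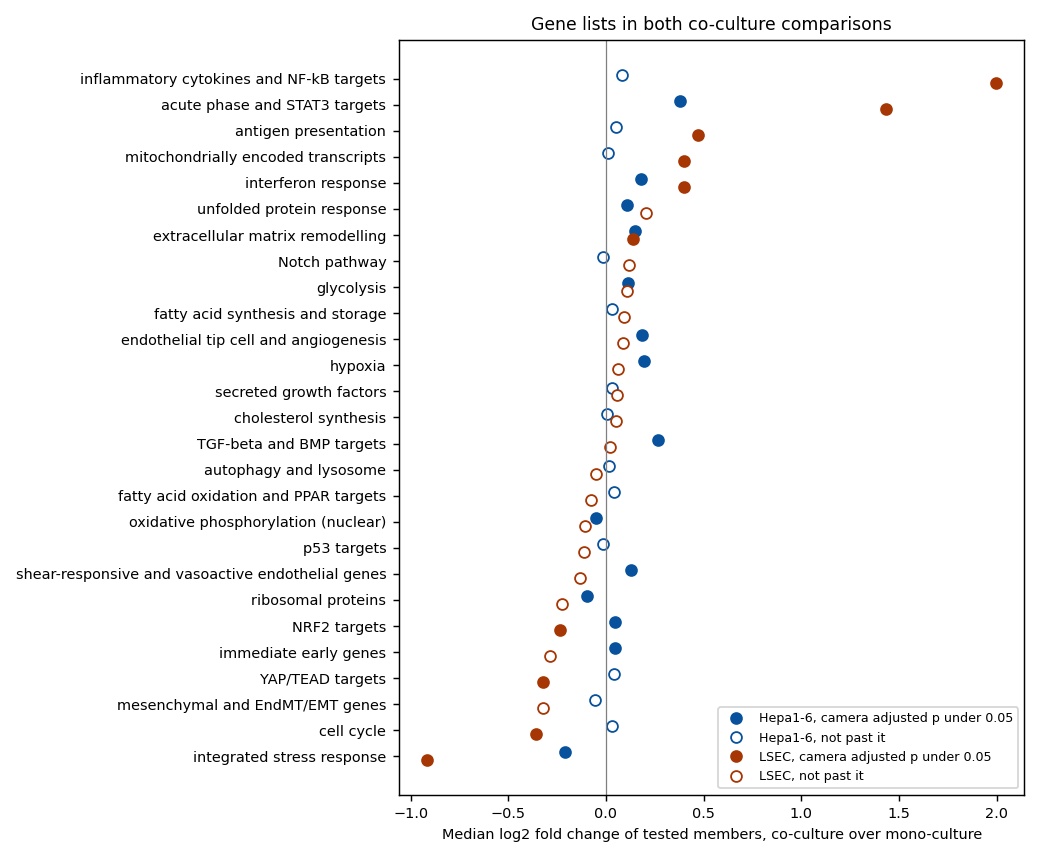
Median log2 fold change (co-culture over mono-culture) of the tested members of 27 pathway lists in Hepa1-6 cells (blue) and LSECs (brown), with filled dots where camera's adjusted p was under 0.05 at the preset correlation. The inflammatory list had a median of 2.00 in LSECs and 0.08 in Hepa1-6 cells, and the integrated stress response list -0.91 and -0.21.

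The co-culture effects were then compared between the cell types. edgeR found 408 of 17346 genes whose effect differed, 165 higher and 243 lower in Hepa1-6 cells relative to LSECs, and 3008 genes (1384 and 1624) with the replicate block. This test shared each gene's dispersion between the cell types. The square root of the common dispersion was 0.205, against 0.043 in the Hepa1-6 fit and 0.276 in the LSEC fit. With that sharing the Hepa1-6 calls fell to 41 and the LSEC calls rose to 1443. The 408 may therefore miss differences driven by Hepa1-6 cells and overcall those driven by LSECs. The most certain differences toward Hepa1-6 cells were Ass1, the phosphatase gene Dusp14, Il11, Ramp3 and Arhgap19, by 3.49, 1.91, 5.39, 5.62 and 2.39 on the log2 scale. Those toward LSECs were Mmp9, Mmp13, Cxcl1, Cxcl5 and the prostaglandin E synthase Ptges, with differences of -6.18, -3.88, -3.75, -4.38 and -5.07. Without any 1 Hepa1-6 library the count was between 216 and 243, and without LSEC mono-culture replicate 1 it was 726.

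Calls were shared between the cell types more often than independent lists would share them. Of 12742 genes tested in both, 47 rose in both, where 15 are expected, and 19 fell in both, where 6.5 are expected. Fisher's exact test gave odds ratios of 4.04 (95% interval 2.81 to 5.72, adjusted p = 2.94e-12) and 3.51 (1.98 to 5.95, adjusted p = 3.6e-05). With the block in the LSEC fit the shared counts were 345 and 390, with 171 and 174.8 expected. Genes that rose in Hepa1-6 cells and fell in LSECs numbered 16, where 7.4 are expected (adjusted p = 0.00367), and those with the opposite pattern 10, where 13.4 are expected (adjusted p = 0.391). With the block, these counts were 171 and 104, where 196.9 and 151.7 are expected, so that the first was no longer above expectation. Genes that rose in both included C3, Cp, Socs3, Nfkbia, Tnfaip3, Cyp1a1 and Id2, and those that fell in both included Mthfd2, Slc7a5, Slc6a9, Psat1, Chac1, Trib3, Atf5 and Gpnmb. Across genes, which are not independent replicates, the log2 fold changes of the cell types had a Spearman correlation of 0.178.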

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

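The tests of macrophage share and hepatoma carry-over for the inflammatory genes, and of transcript length for replicate 1, were chosen after the result was seen, as were the fits with replicates 2 and 3 only.

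Results were singled out where the co-culture effect differed between the cell types by the test of that difference. This held for 408 genes. Of 40 genes named by size of change in a cell type 16 passed. Their choice by large changes in these same libraries favours a difference, so the 16 are no independent support. All 16 passed with the replicate block too, as did all 408 genes. Another 5 (Dusp14, Mmp13, Cxcl1, Cxcl5 and Ptges) were named by their p in that test and so passed by selection. On the log2 scale, as Hepa1-6 effect minus LSEC effect, the differences were 5.39 for Il11, 5.62 for Ramp3, 3.49 for Ass1, 2.77 for Dclk1, 0.80 for Cyp1a1, 2.36 for Lgals3, 2.39 for Arhgap19, 2.19 for Cd300lb, 1.66 for Gpnmb, 1.77 for Atf5 and 1.91 for Dusp14. They were -6.14 for Ccl20, -1.02 for Pdgfb, -0.80 for Gas6, -6.18 for Mmp9, -6.03 for Cxcl3, -5.60 for Csf3, -3.88 for Mmp13, -3.75 for Cxcl1, -4.38 for Cxcl5 and -5.07 for Ptges. By camera, 11 lists differed. Those lower in Hepa1-6 cells relative to LSECs were the interferon response (adjusted p = 0.0191), antigen presentation (0.000833), inflammatory cytokines (1.02e-36), acute phase (8.34e-09), matrix remodelling (0.0495, or 0.469 with the block) and mitochondrially encoded (0.000115) lists. Those higher were cell cycle (2.01e-06), integrated stress response (3.96e-14), NRF2 targets (0.000184), YAP/TEAD targets (6.42e-07) and immediate early genes (0.00404). With an estimated correlation 6 lists passed, and the others had adjusted p = 0.231 (interferon response), 0.376 (antigen presentation), 0.62 (matrix remodelling), 0.0545 (mitochondrially encoded) and 0.0719 (YAP/TEAD targets). With an estimated correlation and the block, antigen presentation passed (adjusted p = 0.0321), while the inflammatory (0.0569), acute phase (0.0876) and immediate early (0.399) lists did not. The interferon list had a median of -0.126 and a mean of 0.014.

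Inflammatory genes were higher in co-cultured LSECs, with 23 of 34 past the threshold. Of the abundant macrophage markers 5 fell and 10 rose with the replicate block, from -2.02 to 4.52 on the log2 scale. Without the block 2 fell (Cd5l and Vsig4) and 3 rose. The blocked fit called 2532 of 15256 genes lower, so some of its falls are expected in any list. A larger share alone would move the markers together, so the spread of their changes argues against it as the whole source. A larger share as a part of the source and a change of state within the macrophages stay open. The median carry-over was 0%, and even at the highest summed level (0.597%, which includes what LSECs alone show) hepatoma RNA would supply at most 8.97% of the rise of any of the 23 genes. With replicates 2 and 3 only, all 23 passed in the same direction. So did all 471 genes called in LSECs, so this is not particular to the list. Which of the cells in the well responded, and to what, was not tested.

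Part of the integrated stress response list was lower in both co-cultures, with 9 members past the threshold in both cell types. Transcript length and GC content are argued against as the whole source, since the list medians (-0.21 and -0.91) lay at percentile 0 of 10000 lists matched on expression, length and GC, whose lowest medians were -0.109 and -0.345. The list median in LSECs was -0.914 with replicates 2 and 3 only, so replicate 1 does not carry it. A difference in nutrients or cell density between wells cannot be told apart from an effect of the other cell, because no value in the files measures it. The calls by camera were lost with an estimated correlation (adjusted p = 0.1 and 0.0957).

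Replicate 1 of the LSECs stood apart in both cultures. Across 15256 genes, its shift from the mean of replicates 2 and 3 had a Spearman correlation with transcript length of -0.685 in mono-culture and -0.683 in co-culture. The shortest 10% of genes were higher by a median of 1.00 and 0.80 log2 and the longest lower by -0.80 and -0.73, and 39 of 40 ribosomal protein genes were at least 1.5-fold higher in both cultures. The shifts of both cultures correlated at 0.75, at 0.602 after a smooth trend on length was removed and at 0.741 after one on GC content. The small drop with GC content argues against it as the whole source. Length was the median over a gene's annotated transcripts, not of those expressed, so the 0.602 cannot decide whether length is the whole source. A part through length remains. A larger macrophage share stays open. Of 18 abundant macrophage markers, 9 were at least 1.5-fold higher in replicate 1 of both cultures and 2 were lower. Their median shifts (0.60 and 0.64 log2) were smaller than those of ribosomal proteins (1.21 and 0.93). The markers were not matched on transcript length, so their shift cannot decide on the macrophage share. The labels give no batch or preparation for replicate 1.

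Other splits of the samples bear on each count. For Hepa1-6 cells, the 10 splits of 6 libraries are too few for a share under 0.05; the real split gave 2298 genes and the highest other 2. For LSECs the numbers were 471 and 0, with 0 also the highest among the 3 other splits that part all same-numbered pairs, and for the mono-cultures 11487 and 0; in each case 1 of 10 splits, the real one, gave as many. For the difference between cell types, 1 of 60 drawn splits, the real one, gave as many genes (408, highest other 323). It was also 1 of the 29 that part all same-numbered LSEC pairs, a share of 0.034. Splits that mix both cell types also remove the co-culture effect of each, and the 29 repeat a few LSEC groupings. They therefore cannot decide whether a difference between the cell types of this size arises by chance. The 8 other splits that kept the LSEC groups and mixed the Hepa1-6 libraries gave 266 to 323 genes, and those that parted the pairs and mixed the LSEC groups at most 4. Much of the count thus follows the LSEC grouping, and the 8 splits are too few to weigh the Hepa1-6 grouping by itself.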

How the results depend on the processing

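The direction of every named gene past the threshold held under each alternative run for it. So did that of every list called in a co-culture comparison. For those lists only an estimated correlation, fry, the block, leave-outs and the replicate 1 fits were run. The 11 lists that differed between the cell types were run only with an estimated correlation, fry and the block. Calls were lost mainly where the spread was estimated another way or a library was left out. Fits with replicates 2 and 3 only, those with a term for LSEC replicate 1 and the overlap with blocked LSEC calls were chosen after seeing the data. The Hepa1-6 count of 2298 genes became 1287 with limma on log2(TPM + 1), 111 at 2-fold or more by construction, and 41 with one dispersion shared by all 12 libraries, where the LSEC libraries' larger spread enters. Without 1 library it lay between 1583 and 2165. With the replicate block it was 2536; no Hepa1-6 library correlated best with its own number. The LSEC count of 471 became 1061 with DESeq2, 1443 with the shared dispersion, 5082 with the replicate block, 5559 with replicates 2 and 3 only and 5801 with a term for replicate 1. Without 1 library it lay between 146 and 490. The block removes the part of the replicate spread that both cultures share. The simulated data gave both cultures the same replicate effect, so they do not vouch for the blocked calls here. In the real LSEC libraries the shifts of replicate 1 correlated at 0.75 between the cultures. In replicate 1, 1420 genes were at least 2-fold higher in mono-culture and 726 in co-culture. The mono-culture count of 11487 stayed between 10428 and 14452 without 1 library and was 10631 with the replicate block. The count of genes that differed between the cell types, 408, became 1056 with DESeq2, 3008 with the replicate block, 2694 with replicates 2 and 3 only and 3503 with a term for LSEC replicate 1; without 1 library it lay between 216 and 726. On LSEC data simulated without the replicate structure 36.6% of DESeq2 calls were false, against 10.2% with edgeR. DESeq2 was not run on simulated data with that structure, so these shares do not weigh its 1061 calls. The cause of the changes with limma was not tested. With an estimated correlation, 2 lists passed in each co-culture comparison in place of 14 and 10, and with the replicate block 15 (YAP/TEAD targets added, adjusted p = 0.0318) and 11. With both, the Hepa1-6 acute phase and TGF-beta lists were no longer past the threshold (adjusted p = 0.385 for both). For the difference between the cell types the block added cholesterol synthesis (adjusted p = 0.0268, or 0.399 with an estimated correlation, against 0.0664). Of the called lists, Hepa1-6 oxidative phosphorylation was lost by camera without co-culture replicate 3 (adjusted p = 0.237) or mono-culture replicate 2 (0.0577). In LSECs NRF2 targets were lost without co-culture replicate 2 or 3 (0.0939 and 0.0938) or mono-culture replicate 1 (0.152), matrix remodelling without mono-culture replicate 1 (0.412) and cell cycle with replicates 2 and 3 only (0.0991). Fry tests against no change, so it does not decide on camera's calls. By fry, Hepa1-6 oxidative phosphorylation (adjusted p = 0.115) did not pass. Nor did the LSEC antigen presentation (0.109), matrix remodelling (0.0693), NRF2 (0.109) and YAP/TEAD (0.0554) lists. It called 20 lists in Hepa1-6 cells and 11 in LSECs, of which 7 and 5 were not called by camera. The LSEC ribosomal list, not past the threshold, passed without co-culture replicate 1 (0.000484), without mono-culture replicate 2 or 3 (0.00828 and 0.00469) and with a term for replicate 1 (0.00786). So did LSEC oxidative phosphorylation without co-culture replicate 1 (0.017) and hypoxia without co-culture replicate 3 (0.0339). The LSEC unfolded protein response passed without mono-culture replicate 1 (0.0308) and with replicates 2 and 3 only (0.0225). With replicates 2 and 3 only, the LSEC shear-responsive list passed too, with the direction down (0.00678). In Hepa1-6 cells secreted growth factors passed without co-culture replicate 3 (0.0024), and YAP/TEAD targets without co-culture or mono-culture replicate 1 or 2 (0.0432 to 0.045). Of 115 named Hepa1-6 genes, 15 passed with the shared dispersion, and of 60 named LSEC genes 40 passed with limma. Without co-culture replicate 1, 2 or 3 the number was 46, 30 and 29, and without mono-culture replicate 1, 2 or 3 it was 53, 34 and 35. The shared calls of the cell types numbered 34 higher and 15 lower among genes under 4-fold apart. The median carry-over stood at its floor of 0% throughout, while the summed measure in LSECs went from 0.275% to 0.597% down to 0.0189% to 0.0782% with diagnostic genes at least 1000-fold apart. Depth limits values under about 0.1 CPM.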

Other observations

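The test of the endothelial genes and the count of aryl hydrocarbon receptor targets with the replicate block were chosen after the result was seen, and of the target genes Cyp1b1, Tiparp and Ahrr fall outside the rule for named genes.

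Hepatic genes absent from the account so far rose in co-cultured Hepa1-6 cells. Apob went from 47.3 ± 2.74 to 75.3 ± 2.04 CPM and Rbp4 from 486 ± 6.4 to 615 ± 21.6 CPM. Hnf4a, a hepatocyte transcription factor, went from 66.3 ± 1.48 to 81.5 ± 2.14 CPM. Of 19 hepatoma and hepatocyte secretory markers tested in LSECs 0 passed without the block, while 1 rose and 3 fell with it.

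H2-K1 had no count in any Hepa1-6 mono-culture library, which allows up to 0.0689 to 0.0858 CPM per library, while the related H2-D1 was at 534 ± 15.0 CPM there. In LSECs alone they were at 1344 ± 379 and 1977 ± 444 CPM. Reads shared between class I genes limit both values.

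Mitochondrially encoded transcripts took 5.05 ± 0.0386% of counts in Hepa1-6 cells alone and 5.15 ± 0.0979% in co-culture. In LSECs they took 1.34 ± 0.152% alone and 1.76 ± 0.142% in co-culture.

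The continuous, arterial and venous endothelium list had 4 members higher in co-cultured LSECs (Selp, Sele, Ackr1 and Cd34). Whether a response of the macrophages alone lay behind them cannot be told apart from a response of the endothelium, because the same 4 genes raised the question.

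Cyp1a1, the best known target of the aryl hydrocarbon receptor, rose in both cell types, from 96.4 ± 3.52 to 388 ± 20.7 CPM in Hepa1-6 cells and from 313 ± 24.7 to 729 ± 79 CPM in LSECs (adjusted p = 1.37e-17 and 0.0106). A medium-borne receptor ligand in the co-culture wells may act on both, as a hypothesis. Of the targets Cyp1b1, Tiparp, Ahrr and Nqo1, 3 passed in Hepa1-6 cells and 0 in LSECs. Ahrr was too low to be tested in Hepa1-6 cells, at 0.0663 ± 0.0662 CPM alone and 0.0501 ± 0.0868 CPM in co-culture. A rise of all 4 in both cell types had been set to count for the hypothesis, so that outcome could not occur. Fewer than 2 in either cell type had been set in advance to count against the hypothesis, so by that rule it failed. The fit without the block may have been too weak for the rule in LSECs. It recovered 0% of 2-fold changes on simulated data with the replicate structure. Those data favour the blocked fit, however, and in the real LSECs Cyp1a1 itself passed without the block at a log2 fold change of 1.18. The blocked fit was turned to after this 0, and by it 3 of the 4 passed in LSECs (Cyp1b1, Ahrr and Nqo1), while Tiparp was at 86.8 ± 26.4 and 83.9 ± 17 CPM. The prediction set in advance thus failed in LSECs, and the blocked count, chosen afterwards, cannot reverse that. Given the low recovery, the failure does not exclude the hypothesis either.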
